A study of Schizosaccharomyces pombe with 57 samples.

How the data were processed

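The libraries were ChIP-seq libraries of Schizosaccharomyces pombe, made from 200 pg of input or immunoprecipitated DNA with 11 cycles of PCR, per the labels' protocols. The submitters' processing notes name the genome build ASM294v2 and the tools Trimmomatic 0.39, Bowtie2, SAMtools, deepTools 3.5.4 and R 4.3.0. Bowtie2 2.5.1 is named for all 57 libraries, and Bowtie2 2.5.3 also for 30 of them. The settings of these tools, any filter on duplicate or multiply aligned reads, and the division of immunoprecipitation by input are not given in the sources used here. Heterochromatic repeats of this genome occur in several similar copies, so the treatment of multiply aligned reads affects values there.

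The deposited list of files and checksums names 60 raw read files, which are 2 files for each of 30 libraries, 15 of them inputs, and 15 processed tracks. The list therefore does not cover all 57 libraries. Its counts equal those of the Swi6 set (Flag-Swi6 and p18-p24 Swi6 with their inputs), which has 30 libraries and 15 inputs. The listed names were not matched to single libraries. The names of all 15 tracks hold the words for scaled CPM, and the only bin size read from these names was 10 bp. The tracks themselves were not analysed here. All 75 checksums differ, so no 2 of the listed files are byte-identical. This excludes only exact copies of a file. The other file holds the allowed instrument models and library strategies of the submission form, describes no sample and was not used. None of the deposited columns used here holds counts, coverage or another measured unit.

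Libraries were grouped by antibody and genotype from their titles, which gave 19 groups of 3. The titles of the 3 inputs of the p18-p24 immunoprecipitation in the double mutant do not name p18-p24, so these were grouped by their library names. Replicate letters were taken from the same label as the group. Before the data were examined, limma tests on log2 ratios of immunoprecipitation over input and exact permutation tests for named regions had been planned. The plan held no replicate block. The rule for named items had fixed the mating-type locus, the pericentromeric repeats, the subtelomeres, 3 islands of facultative heterochromatin, act1 as a control, and the 10 genes or bins with the largest change. None of these tests was run and no item was named under the rule, because the files examined hold no values per position or gene.

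The swi6 gene model was read from the RefSeq annotation of build ASM294v3, which is another version than the build in the submitters' notes, and no coordinate was carried between the builds. The coding sequence was extracted and translated with Python 3.11.15 and Biopython 1.88, and codons 18 and 24 were located in it.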

Results

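Chromatin immunoprecipitation followed by sequencing (ChIP-seq) was carried out in the fission yeast Schizosaccharomyces pombe on 57 libraries, of which 33 were immunoprecipitations and 24 were inputs without antibody. No measurement of enrichment was analysed here: the 2 files examined hold a list of file names with checksums and the drop-down entries of a submission form, and 0 of the entries in the file list is a measurement. Consequently no value, fold or test is given for any gene, heterochromatic region or genotype, and the depth of the libraries is unknown.

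The study asked how phosphorylation of Swi6, the HP1 family protein of fission yeast that binds methylated lysine 9 of histone H3, bears on the activity of Clr4, the Suv39 family enzyme that places this methylation, and on the spreading of the trimethylated form. In the reference genome (build ASM294v3), swi6 (SPOM_SPAC664.01C) lies on chromosome I from 1702406 to 1704098 on the minus strand. It is annotated with 1 exon, and its coding sequence runs from 1703015 to 1704001 and encodes 328 residues. The labels name the substitutions S18A and S24A, in which the reference residue comes first. The labels do not state the numbering, and positions were counted here from 1 at the initiator methionine. The reference coding sequence then has a serine codon at both, that is, at 2 of the 2 labelled positions. Counted from the residue after the methionine, positions 18 and 24 hold valine and glutamate. Of these 2 ways of counting, only that from the methionine matches the labels. That match was required when the codons were read, so it is no independent support for the numbering. Codon 18 occupies 1703948 to 1703950 and codon 24 occupies 1703930 to 1703932, both in the coding part of the single exon.

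The first set of 27 libraries addressed the level of dimethylated and trimethylated lysine 9 of histone H3 (H3K9me2 and H3K9me3) with and without these serines. It covered 3 genotypes: wild-type swi6, a deletion of swi6, and the S18A S24A double mutant. Each genotype had 3 H3K9me2 libraries, 3 H3K9me3 libraries and 3 inputs, and the strains carried a reporter of heterochromatin spreading at the mating-type locus. The 3 replicates of a genotype all carried 1 strain number, which was 814 for wild type, 807 for the deletion and 851 for the double mutant. The labels do not say whether the replicates were separate cultures.

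The second set of 30 libraries addressed where Swi6 itself, and Swi6 recognised by the p18-p24 antibody, was bound. Flag-tagged Swi6 was immunoprecipitated with an anti-Flag antibody from wild type, from the S18A S24A double mutant and from a genotype labelled S6/A, with 3 libraries and 3 inputs for each. Every replicate of these 3 Flag groups came from a strain with its own number. The p18-p24 immunoprecipitation was made from wild type and from the S18A S24A double mutant, again with 3 libraries and 3 inputs for each genotype. All 3 wild-type replicates in this comparison had strain number 814, whereas the double mutant replicates had the numbers 851, 858 and 859. Their titles do not say whether these wild-type replicates were separate cultures.

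An input with the same strain number and replicate letter exists for all 33 immunoprecipitations. In the H3K9 methylation set the same 9 inputs serve both marks, so the planned H3K9me2 and H3K9me3 ratios share them. The H3K9 methylation and Swi6 sets differ in more than the antibody. The cells of both sets were grown at 32 °C, but those of the Swi6 set were then held at 18 °C for 2 hours before fixation. Formaldehyde was used at 1% in both sets, for 15 minutes in the H3K9 methylation set and for 30 minutes in the Swi6 set, where 1.5 mM of the crosslinker EGS was applied first. Comparisons between genotypes under 1 antibody do not cross these conditions, and comparisons of a histone mark with Swi6 binding do.

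The comparisons between genotypes that the design implies, under 4 antibodies, were not computed because the files examined hold no measurement. They are H3K9me3 and H3K9me2 in the deletion and the double mutant against wild type, Flag-Swi6 in both mutants against wild type, and p18-p24 Swi6 in wild type against the double mutant. In the plan, the double mutant was the control strain of the p18-p24 antibody. A lower p18-p24 signal in that mutant would therefore not by itself show less bound Swi6. With 3 libraries in each group, a two-sided exact permutation test of 1 region cannot give a p below 0.10. Each genotype of the H3K9 methylation set had 1 strain number, so genotype could not be told apart from strain there. The same holds for the wild type of the p18-p24 comparison.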

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

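The reference Swi6 had serine at 2 of the 2 labelled positions when residues were counted from the initiator methionine. It had serine at 0 of 2 when they were counted from the residue after it, an alternative chosen after seeing the data. The labels name serine at both positions, so only the count from the methionine matches them. That match was required when the codons were read, so the count is a check of the numbering. It rests on the reference genome and on no deposited measurement. Other scalings, pseudocounts and omissions of a replicate were not run, since the files examined hold no measurement of enrichment. No paired analysis was possible because the count of serines comes from no test.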
